A study of Mus musculus with 9 samples.

How the data were processed

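RNA of mouse hearts was sequenced in 9 libraries, 3 from each of 3 groups: control mice, mice given doxorubicin, and mice given doxorubicin with the gut bacterium Akkermansia muciniphila, called co-treated below. Per the labels' protocols, the animals were C57BL/6 mice, doxorubicin was injected into the peritoneum at 5 mg/kg once a week for 4 weeks to a cumulative 20 mg/kg, and the bacterium was given by gavage in 150 µl of suspension over 4 weeks. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was purified and fragmented, libraries kept strand information through dUTP, and the adapters carried unique molecular identifiers. Whether those identifiers were used in counting was not given in the sources used here. Each library was labelled with its group and a number, and each was taken as a separate heart. Numbers 2 and 4 recur in the doxorubicin and co-treated groups, and number 3 in the control and co-treated groups.

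The authors deposited whole-number estimated counts per Ensembl transcript for all 9 libraries. That the values are estimated counts was read from the deposited values, in which fragments shared by isoforms, or by mitochondrial genes and their nuclear copies, were divided between them. The aligner, the quantifier, the genome build and the annotation behind the deposited counts were not given in the sources used here. The values were already whole, so rounding changed nothing. At low values 2 and 4 were more frequent than their neighbours. A fragment may therefore stand for more than 1 count, which was not tested. For this reason no counting intervals were made except a floor of 3 counts per library for genes at 0 in every library of a group, which covers counting error only.

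Transcripts were summed to genes with the GENCODE M21 annotation of mouse build GRCm38. Of 142604 transcripts, 141374 matched it and 1230 did not. The unmatched transcripts held 0.474% to 0.756% of each library's counts and were tested apart from the genes. The result was 55174 genes, of which 213 share their symbol with another gene. Positions are 1-based GRCm38 coordinates from that annotation. Library totals were 47712133 to 65462194 counts, and 17465 to 18696 genes had at least 10 counts in a library. Over the more abundant transcripts, at most 6.06% had the same value in any pair of libraries, so no library was taken as a repeat of another.

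The main test was edgeR 4.0.16 under R 4.3.3, with its quasi-likelihood fit and F test, robust dispersion, TMM scaling, its default filter on low counts by group, and a single model with a term per group over all 9 libraries. The model covered 18959 genes, and its common dispersion was 0.082, a biological coefficient of variation of 0.29. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. Fold changes are given on the log2 scale, with a standard error taken from the fold change and its F statistic. CPM values, counts scaled to the library size, were computed on TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

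A total of 26 pathway lists and 22 cell type marker lists, with 913 gene names, were fixed with the tests, the alternatives and the rule for named genes before the data were examined. By symbol 905 names matched, 5 were second names of genes already listed and 3 matched no gene. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and p-values were adjusted over the 45 lists and 3 comparisons together. The brown adipocyte, lung epithelium and thymus lists had fewer members tested and were not run in this fit. The brown adipocyte list reached 5 members in the fits without a library, except the fit without doxorubicin library 6, and was run and adjusted with the others there, without a call. With the correlation estimated for each list, camera called 0 lists in any comparison, at lowest adjusted p-values of 0.48, 0.36 and 0.24 for doxorubicin against control, co-treated against doxorubicin and co-treated against control. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 14, 17 and 5 lists. With doxorubicin, fry did not call the camera-called contractile, fatty acid oxidation, PPAR alpha and heat shock lists. Nor did it call the macrophage, neutrophil, T and NK cell and erythroid lists. In co-treated against doxorubicin hearts it left out the contractile, matrix, fatty acid oxidation, PPAR alpha and both oxidative phosphorylation lists, nuclear and mitochondrially encoded. The cell cycle, fibroblast, neutrophil and platelet lists were left out there too. Members of a list were also adjusted over the list alone.

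Named genes were the 12 with the largest rise and the 12 with the largest fall per comparison among those past the test, with all 3 libraries of one group above all 3 of the other and a mean of at least 5 CPM over the 6 libraries. Clone names, predicted models and immunoglobulin and T cell receptor segments were skipped. One gene that met this rule is not reported here. Members of described lists were added, as were the 5 most abundant genes and Nppa, Nppb, Myh7, Cdkn1a, Top2b, Abcb8, Ppara and Ppargc1a.

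Genes changed in both doxorubicin against control and co-treated against doxorubicin were counted by direction. Both comparisons use the same doxorubicin libraries, so 20 sets of unchanged groups that share them were simulated. Other analyses chosen beforehand were DESeq2 1.42.0, other scalings, mitochondrial genes left out, other filters on low counts, only the 6 libraries compared, fold thresholds, the label's number as a block, and each library left out in turn. Alternatives added after seeing the data were a smooth trend with transcript length removed from each library (lowess span 0.3), all libraries thinned to the smallest total, and protein-coding genes alone. Transcript length was the mean annotated length of a gene's transcripts weighted by their counts.

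The procedure was also tested on simulated counts for the 18959 genes. This test was made after the real counts had already been fitted. In each simulated comparison 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. For doxorubicin against control, over 18959 genes, 6% of the 1.5-fold, 49.3% of the 2-fold and 84.8% of the 4-fold changes were recovered. For co-treated against doxorubicin, over 18959 genes, the shares were 10.4%, 50.7% and 89.4%, and for co-treated against control, over 18959 genes, they were 16.4%, 68.7% and 87.9%. Among all called genes, 8 of 105, 6 of 110 and 7 of 124 had not been changed. The real comparisons called other numbers of genes, and the cutoff of the adjustment depends on that number. The recovered shares therefore do not give the sensitivity in the real data. In each comparison a planted list of genes raised 1.5-fold was called upward and 0 of 20 unchanged lists were called. Each gene was simulated independently, so these lists cannot show how camera behaves when the genes of a list vary together. A length trend planted in the doxorubicin libraries gave 221 calls among the 18959 genes for doxorubicin against control, and 0 after its removal.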

Results

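Messenger RNA was measured by sequencing in the hearts of 9 C57BL/6 mice, an inbred laboratory strain. There were 3 control hearts, 3 hearts of mice given doxorubicin, an anthracycline chemotherapy drug that damages the heart, and 3 hearts of mice given doxorubicin with the mucus-degrading gut bacterium Akkermansia muciniphila, called co-treated. The control libraries held 60050304, 64607343 and 58203910 counts. The doxorubicin libraries held 60539244, 49774647 and 47712133, and the co-treated libraries 65462194, 64077066 and 58601240. Mitochondrially encoded mRNAs took 29.4%, 33.9% and 31.6% of the control counts, 27.9%, 25.5% and 24.0% of the doxorubicin counts, and 31.2%, 27.3% and 29.1% of the co-treated counts. The 5 most abundant genes were mt-Co1, mt-Cytb, mt-Co3 and mt-Nd1, which encode subunits of respiratory complexes, and Gm28437, a nuclear copy of mitochondrial sequence. Values of mt-Co3 and Gm28437 are uncertain, because reads from near-identical copies can be divided between them. In co-treated hearts mt-Co1, mt-Cytb, mt-Co3, Gm28437 and mt-Nd1 did not pass the edgeR test against control, at adjusted p-values of 0.607, 0.616, 0.911, 0.951 and 0.956 and log2 fold changes of -0.14, -0.15, 0.03, -0.02 and -0.02.

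The comparison of doxorubicin with control hearts asks what the drug changed in cardiac gene expression. Nppa, which encodes atrial natriuretic peptide, a hormone made by ventricular muscle under load, rose from 74.0 ± 6.83 to 1716 ± 752 CPM (mean ± SD, n = 3 per group), a log2 fold change of 4.53 ± 0.89 (SE, edgeR adjusted p = 0.0096). Serpina3n, a protease inhibitor of the acute phase, rose from 4.03 ± 2.44 to 58.2 ± 15.7 CPM, a log2 fold change of 3.85 ± 0.41 (edgeR adjusted p = 0.000584). Ppara, the transcription factor that drives fatty acid oxidation, fell from 23.6 ± 5.27 to 3.90 ± 1.08 CPM, a log2 fold change of -2.60 ± 0.24 (edgeR adjusted p = 0.000231). Ryr2, the calcium release channel of cardiac muscle, fell from 1144 ± 11.2 to 364 ± 37.8 CPM, a log2 fold change of -1.65 ± 0.15 (edgeR adjusted p = 0.00019). In GRCm38 Nppa lies on chromosome 4 from 148000722 to 148002079, Serpina3n on chromosome 12 from 104406729 to 104414329 and Ppara on chromosome 15 from 85734983 to 85802819. Serpina3n belongs to a cluster of similar genes, so reads can be divided among them.

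**Figure D1:**
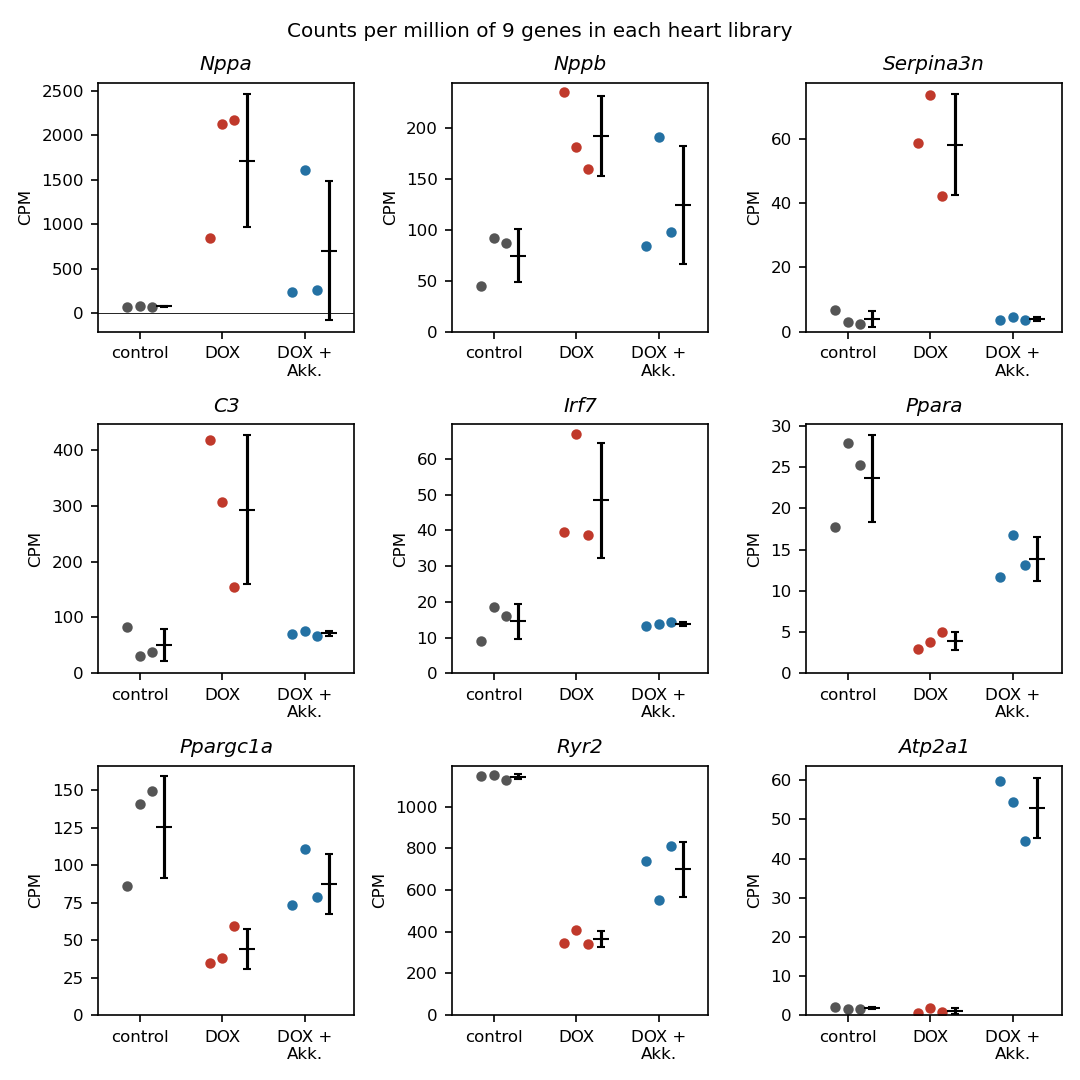
Expression (CPM) of 9 genes in each library, with points for the 3 libraries of a group and a bar for their mean ± SD. Ryr2 averaged 1144 CPM in control, 364 in doxorubicin and 701 in co-treated hearts, and Nppa 74.0, 1716 and 703.

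Doxorubicin against control changed 5084 of 18959 genes by edgeR, 2573 upward and 2511 downward, and 1762 of them by at least 2-fold, 1161 upward and 601 downward. With total library size as the scaling, 3226 rose and 1635 fell, and the median log2 fold change of all genes was 0.16 in place of 0.04. The groups did not overlap for 45.3% of genes, where 10% is expected by chance. Without control library 7 the count was 3308.

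Interferon-stimulated, complement and acute phase, and inflammatory genes were higher after doxorubicin. Of 32 interferon-stimulated genes 27 rose and 0 fell (29 and 0 adjusted over the list alone), among them Irf7, a transcription factor of the interferon response, by 1.74 ± 0.28 on the log2 scale, the peptide transporter Tap1 by 1.69 ± 0.23 and Ifi27l2a by 2.05 ± 0.23. Of 19 complement and acute phase genes 16 rose and 0 fell (17 and 1 adjusted over the list alone), with C4b at 2.89 ± 0.39, C3 at 2.52 ± 0.46 and haptoglobin, Hp, at 3.75 ± 0.33. Of 30 inflammatory cytokine and NF-kB genes 19 rose and 0 fell (22 and 0 adjusted over the list alone), including the adhesion molecules Icam1, at 2.21 ± 0.17, and Vcam1, at 1.62 ± 0.21, and the neutrophil attractant Cxcl1, at 2.77 ± 0.32. The limma camera test called these 3 lists upward at adjusted p-values of 1.03e-11, 1.75e-08 and 2.33e-07 (adjusted p = 0.48 with an estimated correlation for each). The acute phase gene Saa3 had 0 counts in the controls and 2.46 CPM after doxorubicin, at least 45.7-fold higher against a floor of 3 counts per library, and shares sequence with other Saa genes.

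Markers of macrophages, monocytes, neutrophils and endothelial cells were higher in the same hearts, while those of B cells were not. Of 16 macrophage markers 9 rose and 0 fell (9 and 1 adjusted over the list alone), with C1qa at a log2 fold change of 1.20 ± 0.20 and F13a1 at 1.15 ± 0.19. In that list 14 of 16 were above control, with a median log2 fold change of 0.66 but a mean of 0.12. Fry did not call it (adjusted p = 0.0611). Of 14 monocyte and dendritic cell markers 5 rose and 0 fell (6 and 0 adjusted over the list alone), with the chemokine receptor Ccr2 at 2.95 ± 0.55 and Plac8 at 3.78 ± 0.65. Of 13 neutrophil markers 3 rose and 0 fell (3 and 0 adjusted over the list alone), with Csf3r, the receptor of the granulocyte growth factor, at 3.53 ± 0.60. Of 18 endothelial markers 7 rose and 0 fell (7 and 0 adjusted over the list alone), with von Willebrand factor, Vwf, at 1.91 ± 0.17 and the fatty acid carrier Fabp4 at 1.20 ± 0.17. Camera called the 4 lists upward at adjusted p-values of 0.000956, 0.0059, 0.000925 and 0.00803 (adjusted p = 0.55, 0.48, 0.58 and 0.49 with an estimated correlation). Of 13 erythroid markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), and 11 of 13 were above control. Camera called this list upward at 0.039 (adjusted p = 0.72 with an estimated correlation), or 0.14, 0.15 and 0.054 without control library 8, doxorubicin library 4 and doxorubicin library 6. Haemoglobin genes took 0.1475%, 0.1109% and 0.0524% of the control counts and 0.1189%, 0.528% and 0.3504% of the doxorubicin counts. The globin gene Hba-a1, whose reads can be divided with its copy, was at 288 ± 128 CPM in control, 878 ± 562 in doxorubicin and 398 ± 151 in co-treated hearts. Of 28 genes of apoptosis, necroptosis and pyroptosis 10 rose and 2 fell (12 and 2 adjusted over the list alone), with the inflammatory caspase Casp4 at 2.03 ± 0.34, the necroptosis kinase Ripk3 at 1.10 ± 0.22 and Bax at 1.25 ± 0.16, and camera adjusted p = 0.00345 (adjusted p = 0.48 with an estimated correlation).

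Genes of energy metabolism moved in different directions. Of 26 mitochondrial biogenesis and dynamics genes 1 rose and 12 fell (1 and 14 adjusted over the list alone), with the nuclear receptor Esrrg at a log2 fold change of -1.80 ± 0.14, Ppargc1b at -1.79 ± 0.20, its relative Ppargc1a at -1.51 ± 0.27 and the fusion proteins Mfn2 and Opa1 at -0.89 ± 0.12 and -0.98 ± 0.14. Of 26 fatty acid oxidation genes 1 rose and 11 fell (1 and 12 adjusted over the list alone), with Hadha at -0.72 ± 0.17, Acadm at -0.67 ± 0.16 and Crat at -0.70 ± 0.12. Of 13 mitochondrially encoded mRNAs 1 rose and 8 fell (1 and 9 adjusted over the list alone), with mt-Nd5 at -1.41 ± 0.18 and mt-Nd4l at -1.25 ± 0.19. Camera called these 3 lists downward at adjusted p-values of 5.65e-05, 0.000862 and 0.000701 (adjusted p = 0.48, 0.68 and 0.59 with an estimated correlation). Of 17 PPAR alpha targets 1 rose and 4 fell (1 and 7 adjusted over the list alone), at camera adjusted p = 0.0246 (adjusted p = 0.68 with an estimated correlation), or 0.053, 0.06 and 0.16 without control library 3, control library 8 and doxorubicin library 2. Of 39 nuclear oxidative phosphorylation genes 22 rose and 2 fell (23 and 3 adjusted over the list alone), with the short transcripts Ndufa2 at 1.42 ± 0.17 and Cox5b at 1.09 ± 0.13, and with Ndufs1 at -0.89 ± 0.14 and Sdha at -0.66 ± 0.14, at camera adjusted p = 6.51e-08 (adjusted p = 0.58 with an estimated correlation). With the trend by transcript length removed, 7 of these rose and 3 fell, the median log2 fold change went from 0.50 to 0.05, and the call ended at adjusted p = 0.24. The same removal left 0 mitochondrially encoded mRNAs risen and 13 fallen.

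Contractile and stress genes were also affected. Of 24 contractile and calcium handling genes 5 rose and 12 fell (7 and 13 adjusted over the list alone), with the calcium pump Atp2a2 at a log2 fold change of -1.40 ± 0.17, its regulator Pln at -0.71 ± 0.11, the potassium channel subunit Kcnip2 at -1.12 ± 0.19 and troponin C, Tnnc1, at 1.20 ± 0.14. Of 17 cardiac stress and fetal genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), with Fhl1 at 0.85 ± 0.13 and desmin, Des, at 0.82 ± 0.17. Of 18 heat shock and chaperone genes 0 rose and 9 fell (0 and 9 adjusted over the list alone), with Hsph1 at -1.87 ± 0.28 and Hspd1 at -1.09 ± 0.15. Of 17 muscle atrophy and ubiquitin ligase genes 0 rose and 6 fell (1 and 6 adjusted over the list alone), with Trim63 at -1.10 ± 0.17 and Trim55 at -1.10 ± 0.12. Camera adjusted p-values were 0.0144, 0.019, 0.00256 and 0.0168 for these 4 lists (adjusted p = 0.68, 0.48, 0.58 and 0.48 with an estimated correlation). The contractile call ended without doxorubicin library 2 (0.053), the stress call without doxorubicin library 4 (0.058), and the atrophy call with the length trend removed (0.079). With that trend removed, 1 contractile gene rose and 7 fell.

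Among genes named whatever their result, Nppb, which encodes brain natriuretic peptide, rose from 74.8 ± 25.8 to 192 ± 39.0 CPM (log2 fold change 1.36 ± 0.37, edgeR adjusted p = 0.0264), and its adjusted p was 0.053 to 0.079 without control library 3 or 8 or doxorubicin library 2 or 4, 0.093 without the low-count filter and 0.195 with the length trend removed. Myh7, the slow myosin heavy chain, was at 0.80 ± 0.92 (edgeR adjusted p = 0.574), and the cell cycle inhibitor Cdkn1a was at 1.20 ± 0.62 (0.2), so neither passed. Top2b, the topoisomerase that doxorubicin poisons in heart muscle, fell by 0.34 on the log2 scale (SE 0.09, edgeR adjusted p = 0.024). The Top2b adjusted p was 0.056 to 0.099 without control library 3 or 7 or doxorubicin library 4 or 6 and 0.121 with total library size, and its log2 fold change was 0.12 with the length trend removed. Abcb8, a mitochondrial transporter linked to iron export, fell by 0.44 (SE 0.11, edgeR adjusted p = 0.0138), with 0.054 without doxorubicin library 4 and 0.0512 with total library size. Of the abundant genes mt-Cytb fell by 0.51 (0.0167, and 0.051 to 0.075 without control library 7 or 8 or doxorubicin library 6) and mt-Nd1 by 0.41 (0.0372, 0.062 to 0.14 without control library 3, 7 or 8 or doxorubicin library 4 or 6, and 0.0992 with total library size). The mt-Co1 log2 fold change was -0.37 (0.054), and mt-Co3 was at 0.00 (0.999). With the length trend removed mt-Co3 was at -0.62 and passed (edgeR adjusted p = 0.00624).

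Rises and falls were ranked among genes with complete separation of the groups and a mean of at least 5 CPM over the 6 libraries. The largest rises were those of Nppa, Slfn4, Chil3, Serpina3n, Clca3a1, Hp, Csf3r, Csf2rb2, Lgals3, Lcn2, Ccr2 and Cfb, at log2 fold changes from 4.53 down to 2.95. The largest falls were those of Pakap, Lrrc14b, Pm20d2, Ppara, the kinase Hipk2, Pdpr, the mitochondrial folate enzyme Aldh1l2, the integrin subunit Itgb6, the sodium channel subunits Scn4a and Scn4b, the adrenergic receptor Adra1a and mt-Ty, at -5.08 to -2.28. Pakap overlaps other annotated genes, mt-Ty is a short transfer RNA, and Chil3 and Slfn4 have close relatives, so their values are uncertain. Of these, Chil3 lost its call without control library 3 or 8 or doxorubicin library 2, 4 or 6 (log2 fold change 3.89 to 4.66, edgeR adjusted p 0.07 to 0.1), and Cfb without control library 3 or 7 or doxorubicin library 2 or 4 (2.62 to 3.34, 0.051 to 0.069). Scn4b lost it without control library 3 or 8 or doxorubicin library 2, 4 or 6 (-2.46 to -1.83, 0.06 to 0.11), Itgb6 and Scn4a without doxorubicin library 4 or 6 (0.054 to 0.058 and 0.052 to 0.059), and Lcn2 without control library 8 (0.054). Without the low-count filter adjusted p-values were 0.0926 for Chil3, 0.0801 for Cfb and 0.0899 for Scn4b, and with the length trend removed 0.0613 for Chil3 and 0.0545 for Scn4b. With only the 6 libraries compared the Chil3 value was 0.0653.

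The lists in this paragraph were not called by camera in doxorubicin against control hearts. Sex-linked genes and T and NK cell markers were called and are given under other observations. Of 24 p53 targets 4 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.39). Of 30 extracellular matrix genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 0.471, and called upward at 0.01 without doxorubicin library 6). Of 20 iron handling and ferroptosis genes 7 rose and 5 fell (8 and 6 adjusted over the list alone, 0.854). Of 24 glycolysis genes 6 rose and 6 fell (7 and 7 adjusted over the list alone, 0.89, with a median log2 fold change of 0.09 and a mean of -0.02). Of 24 autophagy and lysosome genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, 0.945). Of 25 immediate early genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, 0.146, and called upward at 0.036 without control library 3). Of 22 angiogenesis and growth factor genes 4 rose and 3 fell (5 and 3 adjusted over the list alone, 0.462). Clock genes (1 rose and 2 fell, 0.785), glucocorticoid-responsive genes (3 and 0, 0.646) and stress genes of the ER (1 and 2, 0.814) were not called. Cell cycle genes (1 and 2, 0.192) were called downward without doxorubicin library 4 (0.01). MHC class II genes (0 and 0, 0.0887, downward, 1 of 9 above control) were called downward without control library 8 (0.042), without doxorubicin library 2 (0.02) and with the length trend removed (0.024).

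Among cell markers ventricular (4 rose and 5 fell, camera adjusted p = 0.626), atrial (3 and 0, 0.0757) and smooth muscle genes (3 and 4, 0.417) were not called. Fibroblast genes (3 and 0, 0.118) were called upward without doxorubicin library 6 (0.0055) and with the length trend removed (0.042). B cell and plasma cell genes ran downward (0 and 0, 0.0595), with 1 of 20 above control and a median log2 fold change of -1.01. They were called downward without control library 8 (0.02), without doxorubicin library 2 (0.012) and with the length trend removed (0.031). Platelet (1 and 0, 0.615), mast cell (1 and 0, 0.704), white adipocyte (1 and 0, 0.258) and epicardial genes (0 and 0, 0.252) were not called. Nor were skeletal fibre (2 and 0, 0.873), valve (1 and 1, 0.92) and Schwann cell genes (1 and 0, 0.285, and called upward at 0.038 without doxorubicin library 4).

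Short transcripts were higher and long transcripts lower in doxorubicin than in control libraries. Across 12403 genes, which are not independent replicates, the Spearman correlation of transcript length with log2 fold change was -0.44. The median log2 fold change was 0.69 for 962 genes with transcripts under 1 kb, of which 60.4% rose and 4.3% fell, and -0.37 for 1533 genes over 6 kb, of which 3.8% rose and 42.1% fell. Each library was set against the mean of the control libraries, and each control library against the mean of the other controls. Per doubling of length this log2 ratio changed by -0.190, -0.261 and -0.293 in doxorubicin libraries 2, 4 and 6. It changed by -0.053, -0.087 and -0.077 in co-treated libraries 2, 3 and 4, and by 0.002, 0.035 and -0.036 in control libraries 3, 7 and 8. The control changes cancel out by construction. With the trend removed, 3714 genes passed, of which 3004 were among the 5084 and 2997 kept their direction. The cause of the trend was not tested, and no measure of RNA quality was used here. A technical difference common to the doxorubicin libraries cannot be told apart from the drug.

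**Figure D2:**
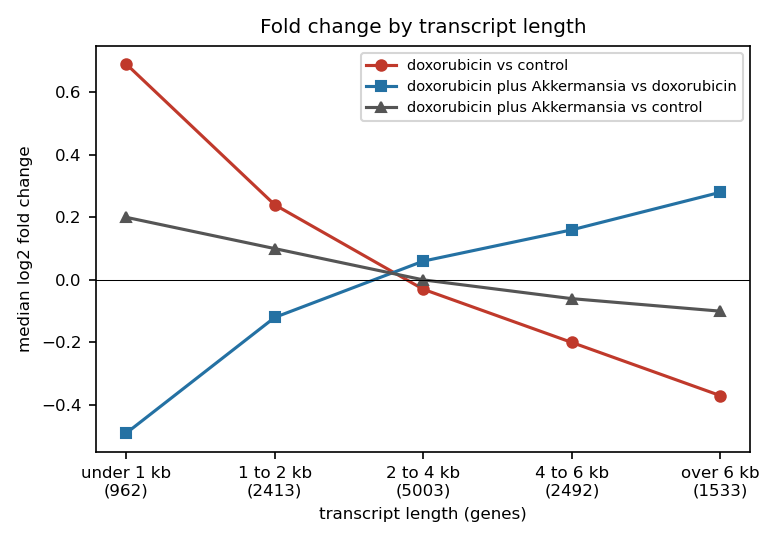
Median log2 fold change of genes grouped by transcript length in kb, for the 3 comparisons. Doxorubicin against control ran from 0.69 under 1 kb to -0.37 over 6 kb.

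The comparison of co-treated with doxorubicin hearts asks how hearts differed when the bacterium was given with the drug. No group was given the bacterium alone. An altered response to the drug therefore cannot be told apart from an effect of the bacterium itself. Serpina3n fell from 58.2 ± 15.7 CPM in doxorubicin hearts to 4.04 ± 0.57 in co-treated hearts, a log2 fold change of -3.85 ± 0.41 (SE, edgeR adjusted p = 0.000755), and Icam1 fell from 41.9 ± 8.05 to 8.37 ± 1.41 CPM, a log2 fold change of -2.33 ± 0.17 (edgeR adjusted p = 0.000101). Ppara rose from 3.90 ± 1.08 to 13.8 ± 2.63 CPM, a log2 fold change of 1.83 ± 0.24 (edgeR adjusted p = 0.000865). Ryr2 rose from 364 ± 37.8 to 701 ± 132 CPM, a log2 fold change of 0.94 ± 0.15 (edgeR adjusted p = 0.0017). Atp2a1, the calcium pump of fast skeletal muscle, rose from 1.05 ± 0.738 to 52.9 ± 7.76 CPM, a log2 fold change of 5.67 ± 0.43 (edgeR adjusted p = 0.000209). In all, edgeR changed 4419 genes, 2233 upward and 2186 downward, or 1456 and 2778 with total library size, which moved the median of all genes from -0.02 to -0.13. By at least 2-fold 495 rose and 1028 fell. The groups did not overlap for 39.4% of genes, where 10% is expected by chance, and the count was 2805 without doxorubicin library 4 and 2635 without co-treated library 2.

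Interferon-stimulated, complement and acute phase, inflammatory and immediate early genes were lower in co-treated than in doxorubicin hearts. Of 32 interferon-stimulated genes 0 rose and 29 fell (0 and 32 adjusted over the list alone), with Irf7 at a log2 fold change of -1.81 ± 0.28 and Ifi27l2a at -2.56 ± 0.24. Of 19 complement and acute phase genes 0 rose and 15 fell (0 and 16 adjusted over the list alone), with C4b at -2.33 ± 0.38 and Hp at -5.13 ± 0.36. Of 30 inflammatory genes 0 rose and 13 fell (0 and 18 adjusted over the list alone), with Cxcl1 at -2.79 ± 0.32 and Vcam1 at -1.29 ± 0.20. Of 25 immediate early genes 0 rose and 15 fell (0 and 18 adjusted over the list alone), with Junb at -1.52 ± 0.23 and Socs3 at -2.16 ± 0.25. Camera adjusted p-values were 1.15e-14, 1.28e-09, 4.94e-07 and 8.18e-08 (adjusted p = 0.48, 0.48, 0.48 and 0.36 with an estimated correlation). Markers of macrophages (0 of 16 rose and 12 fell, with C1qa at -1.77 ± 0.20), monocytes and dendritic cells (0 of 14 and 8), neutrophils (0 of 13 and 5) and endothelium (1 of 18 and 9, with Vwf at -1.62 ± 0.17) were called downward at 1.68e-07, 0.000129, 0.000509 and 0.000503 (adjusted p = 0.48 with an estimated correlation for each). Adjusted over the list alone, these counts were 0 and 12, 0 and 10, 0 and 5, and 1 and 9. Of 28 cell death genes 3 rose and 11 fell (3 and 15 adjusted over the list alone), with Ripk3 at -1.81 ± 0.22, at camera adjusted p = 0.000201 (adjusted p = 0.48 with an estimated correlation).

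Matrix and proliferation genes were lower too. Of 30 extracellular matrix genes 0 rose and 10 fell (0 and 13 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, at -3.78 ± 0.44, elastin, Eln, at -1.34 ± 0.25 and Fstl1 at -1.59 ± 0.29. Of 18 fibroblast markers 0 rose and 6 fell (0 and 6 adjusted over the list alone), and of 32 cell cycle genes 1 rose and 7 fell (1 and 9 adjusted over the list alone). Camera adjusted p-values were 2.13e-06, 0.000823 and 0.000951 (adjusted p = 0.58, 0.58 and 0.68 with an estimated correlation). Fry called none of these lists (adjusted p = 0.0801, 0.0697 and 0.134). Of 8 platelet markers 0 rose and 3 fell (0 and 4 adjusted over the list alone), at 0.0161 (adjusted p = 0.58 with an estimated correlation), or 0.052 without co-treated library 4.

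Genes of mitochondrial biogenesis, fatty acid oxidation and contraction were higher in co-treated hearts, while those of nuclear oxidative phosphorylation were lower. Of 26 mitochondrial biogenesis and dynamics genes 13 rose and 1 fell (16 and 1 adjusted over the list alone), with Esrrg at a log2 fold change of 1.68 ± 0.14 and Ppargc1b at 1.57 ± 0.20. Of 26 fatty acid oxidation genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Hadha at 0.76 ± 0.17 and Acadm at 0.83 ± 0.16. Of 24 contractile and calcium handling genes 13 rose and 1 fell (13 and 2 adjusted over the list alone), with Atp2a2 at 1.03 ± 0.17 and Kcnip2 at 1.04 ± 0.19. Of 13 mitochondrially encoded mRNAs 5 rose and 1 fell (8 and 1 adjusted over the list alone), with mt-Nd5 at 1.14 ± 0.18. Of 17 atrophy genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), with Trim63 at 1.24 ± 0.17, and of 19 clock genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with Per3 at 1.54 ± 0.20 and Nr1d1 at 1.31 ± 0.28. Camera adjusted p-values for these 6 lists were 6.72e-07, 1.95e-05, 0.00412, 0.00562, 0.00197 and 0.00153 (adjusted p = 0.47, 0.58, 0.63, 0.68, 0.48 and 0.48 with an estimated correlation). Of 17 PPAR alpha targets 7 rose and 1 fell (9 and 1 adjusted over the list alone), at 0.0161 (adjusted p = 0.68 with an estimated correlation), or 0.1 without doxorubicin library 2 and 0.15 without co-treated library 2. Of 39 nuclear oxidative phosphorylation genes 3 rose and 20 fell (3 and 22 adjusted over the list alone), with Ndufa2 at -1.09 ± 0.17 and Sdha at 0.81 ± 0.15, at 8.92e-05 (adjusted p = 0.68 with an estimated correlation). With the length trend removed, 3 of these rose and 6 fell and the call ended at adjusted p = 0.53, while 8 contractile genes rose and 1 fell.

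Of 14 markers of skeletal muscle fibres 11 rose and 1, Myl1, fell (11 and 1 adjusted over the list alone), at camera adjusted p = 1.51e-07 (adjusted p = 0.47 with an estimated correlation). The fast myosin heavy chain Myh4 was at 2.26 CPM in control, 0.957 in doxorubicin and 80.5 in co-treated hearts, a log2 fold change of 6.43 ± 1.32 against doxorubicin (edgeR adjusted p = 0.0151). Myh4 is similar in sequence to other myosin heavy chains, so its reads can be divided. Markers tested at up to 10 CPM in heart summed to 242, 214 and 178 CPM in co-treated libraries 2, 3 and 4, against 9.8, 9.82 and 15.4 in the controls and 10.7, 18.5 and 12.1 in the doxorubicin libraries.

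Nppa, at 242.5, 1610 and 257.1 CPM in co-treated libraries 2, 3 and 4, did not pass against doxorubicin (log2 fold change -1.29 ± 0.78, edgeR adjusted p = 0.279), nor did Nppb (84.65, 191.5 and 97.83 CPM, -0.62 ± 0.36, 0.25). Myh7 was at 1546, 14280 and 1238 CPM in the same libraries (1.92 ± 0.94, 0.192), and Cdkn1a at -1.81 ± 0.63 (0.0781). Of 17 cardiac stress and fetal genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), with Fhl1 at -0.85 ± 0.13, at camera adjusted p = 0.0316 (adjusted p = 0.48 with an estimated correlation), or 0.084 without doxorubicin library 4 and 0.071 without co-treated library 4. Abcb8 rose by 0.57 ± 0.11 (edgeR adjusted p = 0.00458). Top2b rose by 0.30 ± 0.09 (0.0434), with 0.055 to 0.16 without doxorubicin library 2, 4 or 6 or co-treated library 2 or 4, and a log2 fold change of -0.04 with the length trend removed. Top2b also missed the threshold with total library size (0.185), without the low-count filter (0.0586), with the stricter filter (0.0673) and with only the 6 libraries compared (0.0842). Ppargc1a rose by 0.99 ± 0.27 (0.0261), with 0.079 to 0.089 without doxorubicin library 2 or 4 or co-treated library 3, 0.0698 without the low-count filter and 0.114 with the length trend removed.

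Rises and falls were again ranked among genes with complete separation and a mean of at least 5 CPM. The largest rises were those of Myh4, Atp2a1, Actn3, Pakap, Lrrc14b, Tnnt3, Mylpf, Pm20d2, Inmt, Asb15, Pdpr and Limch1, from 6.43 down to 2.24 on the log2 scale. Among the largest falls were those of Hp, Chil3, Slfn4, Csf3r, Serpina3n, Timp1, the myelin gene Mbp, Cfb, the stress transcription factor Atf3, the matrix protease Mmp9 and Lgals3, at -5.13 to -2.99. Chil3 lost its call without any of the 6 libraries (log2 fold change -5.95 to -4.48, edgeR adjusted p 0.061 to 0.11), and Inmt without doxorubicin library 2, 4 or 6 or co-treated library 2 or 3 (1.41 to 2.59, 0.059 to 0.14). Cfb lost it without doxorubicin library 4 or co-treated library 2 or 3 (0.056 to 0.084), and Mbp without co-treated library 2, 3 or 4 (0.078 to 0.092). Without the low-count filter adjusted p-values were 0.0778 for Chil3, 0.116 for Inmt, 0.071 for Cfb and 0.0694 for Mbp. Inmt was at 0.0554 with total library size, and Mbp at 0.0605 with only the 6 libraries compared.

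Among lists without a call in co-treated against doxorubicin hearts, of 25 NRF2 and antioxidant genes 2 rose and 8 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.177). Of 24 p53 targets 3 rose and 5 fell (3 and 5 adjusted over the list alone, 0.146), and of 18 heat shock genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, 0.785). Iron handling genes (2 and 5, 0.821) and autophagy genes (5 and 4, 0.661) were not called. Glycolysis genes (7 and 3, 0.196) were called upward at 0.029 without doxorubicin library 6. Stress genes of the ER (1 and 7, 0.0784) were called downward at 0.0042 without co-treated library 3. Angiogenesis genes (1 and 5, 0.0875) were called downward at 0.014 without doxorubicin library 6, 0.029 without co-treated library 4 and 0.039 with the length trend removed. Glucocorticoid-responsive genes (0 and 3, 0.18) were called downward at 0.024 without doxorubicin library 2 and 0.0048 without co-treated library 3. MHC class II genes (0 and 0, 0.29) and mast cell genes (0 and 1, 0.0887) were called downward without doxorubicin library 6, at 0.036 and 0.029. Erythroid genes (1 and 1, 0.0672) were called downward at 0.0014 without doxorubicin library 2 and 0.025 without co-treated library 2. B cell genes (0 and 0, 0.0981) were called upward at 0.016 without doxorubicin library 2 and 0.015 without co-treated library 3. Ventricular genes (5 and 0, 0.41) were called upward at 0.044 without co-treated library 3. Atrial (1 and 1, 0.494), smooth muscle (3 and 3, 0.712), T and NK cell (1 and 1, 0.604), adipocyte (0 and 0, 0.653), Schwann cell (0 and 2, 0.505) and valve genes (0 and 2, 0.203) were not called.

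**Figure D3:**
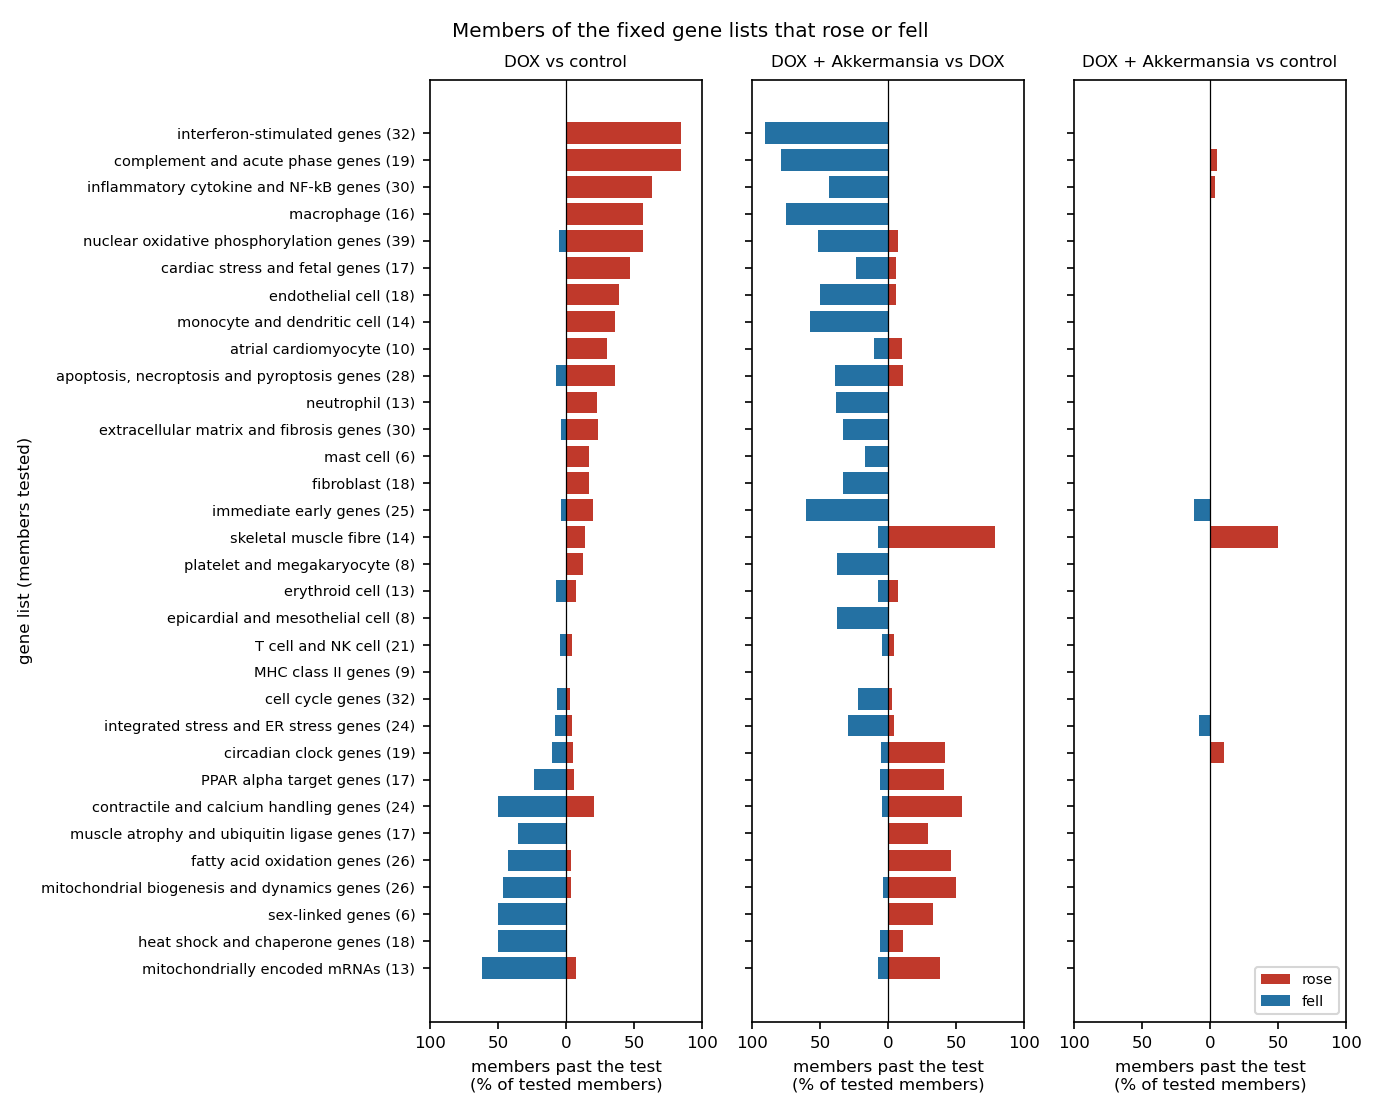
Percent of the tested members of each gene list that rose or fell in the 3 comparisons, for lists called by camera. Of 32 interferon-stimulated genes 27 rose with doxorubicin and 29 fell in co-treated against doxorubicin hearts.

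Genes changed by doxorubicin lay in the opposite direction in the co-treated comparison. Of the 5084 genes, 4960 (97.6%) had opposite signs in co-treated against doxorubicin hearts, among them Ppara, Ryr2, Icam1 and Serpina3n. Of 3081 genes past the test in both comparisons, 3077 had opposite and 4 the same direction. The number was 1947 without doxorubicin library 4 and 1964 without co-treated library 2. Both comparisons use the same doxorubicin libraries, and 20 simulations of unchanged groups sharing them gave 81% opposite signs, at most 81.9%. Genes higher in doxorubicin than in control hearts and lower in co-treated than in doxorubicin hearts numbered 1451, where independent lists would share 297. Those with the reverse pattern numbered 1626, against 296. Part of the excess over independent lists may come from the shared libraries. The correlation of the fold changes across genes was -0.70, against -0.50 simulated, and their covariance -0.84, against -0.18 simulated, a difference of -0.66. With each doxorubicin library held out of the calling and then set against the co-treated mean, 89.7%, 93.2% and 95.2% of the called genes had opposite signs for libraries 2, 4 and 6.

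**Figure D4:**
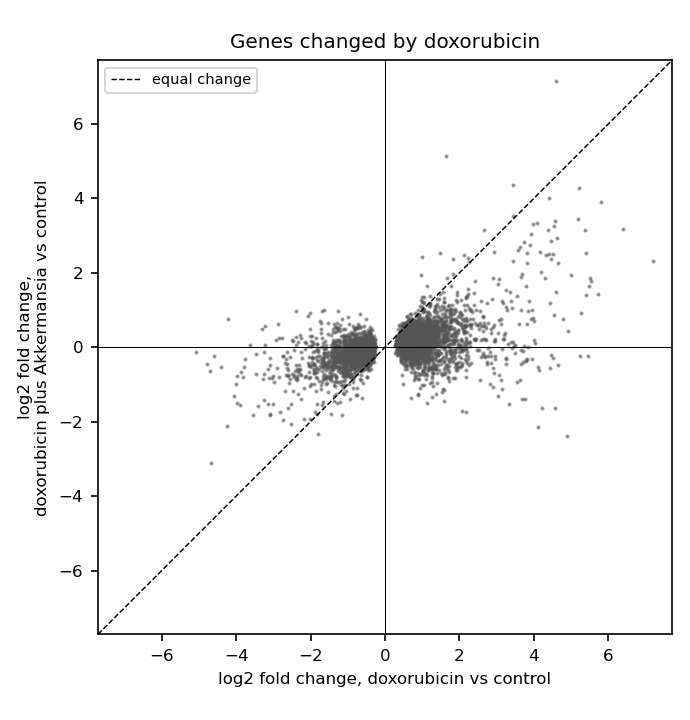
Log2 fold change against control in doxorubicin hearts (x) and co-treated hearts (y) for 5008 of the 5084 genes changed by doxorubicin, with a dashed line for equal change. The other 76 were at 0 in every library of a group, and the median absolute log2 fold change was 0.77 on x and 0.23 on y over the 5084 genes. The genes were chosen by their change on x, which by itself favours a larger median on x.

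The comparison of co-treated with control hearts asks how far co-treated hearts lay from control. Skeletal muscle fibre genes were higher in co-treated hearts: parvalbumin, Pvalb, rose from 0.188 ± 0.0357 to 6.69 ± 1.65 CPM (log2 fold change 5.14 ± 0.33, edgeR adjusted p = 0.000184), Atp2a1 from 1.76 ± 0.32 to 52.9 ± 7.76 CPM (4.91 ± 0.41, 0.00242) and the release channel Ryr1 from 0.382 ± 0.139 to 8.38 ± 0.772 CPM (4.44 ± 0.42, 0.0019). The immediate early gene Jun fell from 64.0 ± 6.73 to 26.1 ± 2.57 CPM (-1.29 ± 0.12, 0.0019). By edgeR 25 genes changed, 16 upward and 9 downward, while 3313 had an unadjusted p under 0.05 and DESeq2 called 940. The count was 103 without control library 3, 8 without control library 7, 12 without control library 8, 9 without co-treated library 2 and 42 without co-treated library 4. It was 102 without the low-count filter and 40 with only the 6 libraries compared. The groups did not overlap for 25.4% of genes, where 10% is expected by chance. Of the 5084 genes changed by doxorubicin, 8 were also called here, and 73.9% had the same sign as with doxorubicin. Both comparisons use the same control libraries, so agreement in sign arises without any effect. Over all genes the correlation of the fold changes was 0.41, against 0.50 simulated for unchanged groups, and the covariance 0.38, against 0.18 simulated. Nppa, at 703 against 74.0 CPM, had a log2 fold change of 3.25 ± 0.83 and did not pass (edgeR adjusted p = 0.148), nor did Myh7 at 2.72 ± 0.97 (0.226), Nppb at 0.74 ± 0.36 (0.339) and Cdkn1a at -0.62 ± 0.61 (0.664). Ppara at -0.77 ± 0.23 (0.154), Ppargc1a at -0.52 ± 0.27 (0.352), Top2b at -0.04 ± 0.09 (0.876) and Abcb8 at 0.13 ± 0.11 (0.571) did not pass either.

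Other genes past the test and named were Actn3, Tnnt3, Mylpf, Tnni2, the clock genes Dbp and Per3, Irx3, Dgkz and Usp54 among the rises, and Phgdh, an enzyme of serine synthesis, Atf3, Fam111a, Sik1, Nedd9, Prrg3, Klf4 and Skil among the falls. Saa3 had 0 counts in the controls and 1.40 ± 0.883 CPM in co-treated hearts, at least 26-fold higher, and its edgeR adjusted p of 0.0481 was 0.051 to 0.19 without control library 3, 7 or 8 or co-treated library 2 or 3, 0.0585 with the length trend removed and 0.0543 with thinned libraries. Among the rises calls ended without control library 7 for Actn3 (0.053 to 0.054, also without control library 8), Tnnt3 (0.053), Dbp and Per3 (0.091 to 0.15 and 0.054 to 0.079, also without co-treated library 2). They ended without control library 7 or 8 or co-treated library 2 for Irx3, Dgkz and Usp54 (0.086 to 0.2, 0.086 to 0.26 and 0.082 to 0.2, for Irx3 and Dgkz also without co-treated library 3). Among the falls, Fam111a lost its call without any of the 6 libraries (0.051 to 0.23), Nedd9 without every library but co-treated library 4 (0.051 to 0.22) and Prrg3 without every library but control library 3 (0.066 to 0.2). Klf4 lost it without control library 7 or 8 (0.054 to 0.06), Skil also without co-treated library 2 (0.054 to 0.073), Phgdh without control library 7 or co-treated library 2 (0.076 to 0.085), Sik1 without control library 8 or co-treated library 2 or 4 (0.064 to 0.14) and Atf3 without co-treated library 2 (0.066). Fam111a was at 0.0501 with total library size, and Prrg3 at 0.0661 with only the 6 libraries compared and 0.0563 with the length trend removed.

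Of 14 skeletal muscle fibre markers 7 rose and 0 fell (11 and 0 adjusted over the list alone), at camera adjusted p = 1.48e-20 (adjusted p = 0.24 with an estimated correlation). Of 25 immediate early genes 0 rose and 3 fell (0 and 11 adjusted over the list alone), and of 19 clock genes 2 rose and 0 fell (8 and 4 adjusted over the list alone), at 8.58e-09 and 0.000154 (adjusted p = 0.24 and 0.47 with an estimated correlation). No single gene passed among 32 cell cycle, 30 extracellular matrix, 18 heat shock, 16 macrophage, 9 MHC class II and 8 epicardial genes (0 and 14, 1 and 8, 0 and 8, 0 and 8, 0 and 0, and 0 and 6 rose and fell adjusted over the list alone), while camera called these lists downward at 1.71e-10, 7.96e-09, 4.78e-08, 2.69e-05, 3.62e-05 and 0.000139 (adjusted p = 0.48, 0.48, 0.48, 0.48, 0.48 and 0.47 with an estimated correlation). Fibroblast (0.00912), platelet (0.00542) and mast cell markers (0.0132) were also called downward with no gene past the test (adjusted p = 0.68, 0.54 and 0.48 with an estimated correlation), the fibroblast list at 0.061 without co-treated library 3 and the platelet list at 0.073 without co-treated library 4. Of 24 integrated stress and ER stress genes 0 rose and 2, Atf3 and Phgdh, fell (0 and 4 adjusted over the list alone), at 0.0132 (adjusted p = 0.58 with an estimated correlation), or 0.21 without co-treated library 2 and 0.074 without co-treated library 4. Oxidative phosphorylation genes (0.000309), T and NK cell markers (0.0169) and atrial markers (0.0385) were called upward with no gene past the test (adjusted p = 0.69, 0.68 and 0.48 with an estimated correlation). The first of these calls ended without co-treated library 4 (0.051) and with the length trend removed (0.41), the T and NK cell call without control library 8 (0.45) or co-treated library 4 (0.093), and the atrial call without control library 7 (0.074) or co-treated library 4 (0.11). The atrial genes Myl7 and Sln were at most 0.264 CPM in co-treated and 0.305 CPM in control libraries. Myl4 was at 0.632, 1.027 and 1.427 CPM in co-treated libraries, against 0.654, 0.429 and 1.147 in controls.

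Other lists were not called in co-treated against control hearts. Of 30 inflammatory genes and 19 complement and acute phase genes 1 rose in each, Saa3, and 0 fell (5 and 1, and 1 and 3, adjusted over the list alone, camera adjusted p = 0.674 and 0.931). No gene passed among interferon-stimulated genes (0.282, and called downward at 0.034 without co-treated library 2). The same was true of fatty acid oxidation genes (0.138, and called upward at 0.015 without control library 3 and 5.2e-05 without co-treated library 3) and glycolysis genes (0.0622, and called upward at 0.017 without control library 3 and 0.033 without co-treated library 2). Mitochondrially encoded mRNAs were at 0.0683, and called downward at 0.0074 without control library 3, 0.0024 without co-treated library 2 and 0.00021 with the length trend removed. Valve genes were at 0.0583, and called downward at 0.023, 0.043 and 0.035 without control library 3, control library 7 and co-treated library 4. Glucocorticoid-responsive genes were at 0.177, and called downward at 0.036 without control library 3 and 1e-05 without co-treated library 3. PPAR alpha targets were at 0.971, and called upward at 0.047 without co-treated library 3, and neutrophil genes at 0.505, and called downward at 0.017 without control library 8.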

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

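The test of transcripts outside the gene annotation was chosen after the data were seen. Of 330 such transcripts with enough counts, 44 changed in doxorubicin against control hearts by edgeR, 8 upward and 36 downward, and 37 changed in co-treated against doxorubicin hearts, 27 upward and 10 downward. They drew attention because they lie outside the genes compared. In co-treated against control hearts 0 changed. No explanation was tested, and these transcripts carry no gene names here.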

How the results depend on the processing

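Removal of the length trend, thinning to the smallest total and protein-coding genes alone were chosen after the results were seen. Of the values of named genes under the alternatives, 6284 kept their side of the threshold, 319 were no longer past it and 92 passed only there. Another 4 changed sign and were past the threshold in the main or the alternative fit. A change of sign in a value past it in neither fit was counted among the 6284. All 4 changed sign with the length trend removed, which took Top2b to 0.12 in doxorubicin against control and to -0.038 in co-treated against doxorubicin hearts, mt-Co3 to -0.62 in doxorubicin against control and Gm28437 to 0.42 in co-treated against doxorubicin hearts (log2). There mt-Co3 and Gm28437 passed the edgeR test (adjusted p = 0.00624 and 0.0249), and Top2b did not in either comparison (0.372 and 0.795). The cause was not tested. A fold threshold of 2 left 1762 genes in doxorubicin against control and 1523 in co-treated against doxorubicin hearts, and with an unadjusted p there were 2469, 2255 and, in co-treated against control hearts, 760, with 1281 opposed genes. Co-treated against control hearts gave 940 genes by DESeq2, 102 without the low-count filter and 40 with only the 6 libraries compared. An estimated correlation called 0 lists in each comparison, and fry 5 in co-treated against control hearts. With each library left out, counts ran from 3308 to 4337, 2635 to 4128 and 8 to 103 genes, 18 to 21, 23 to 28 and 12 to 21 lists, and 1947 to 3301 opposed genes. The lone libraries were control library 7 (3308), doxorubicin library 4 (2805 and 1947 opposed) and co-treated library 2 (2635 and 1964 opposed). In co-treated against control hearts they were control libraries 3 (103), 7 (8) and 8 (12) and co-treated libraries 2 (9) and 4 (42). Numbers 2 and 4 recur in both treated groups, but same-numbered libraries did not deviate together (r 0.07 and 0.02, other pairs -0.13 to 0.15). With the number as a replicate block, 3636 genes and 33 lists changed in co-treated against doxorubicin hearts, with 1 residual degree of freedom. The pseudocount alternative was not run, since it applies to normalized values. With all libraries thinned to the smallest total 5052, 4446 and 28 genes changed. Of the 219 called results of named genes 175 stayed past the threshold with every single library left out.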

Other observations

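The tests of skeletal muscle tissue, of a mislabelled heart, of atrial tissue, of the length trend, of thinned libraries and of the opposed genes shared between fits were chosen after the results were seen. Of 25 NRF2 and antioxidant genes 9 rose and 3 fell with doxorubicin (10 and 3 adjusted over the list alone), although camera did not call the list (camera adjusted p = 0.0691, and 0.043 without doxorubicin library 2). Fry called it upward (fry adjusted p = 0.00881), and downward in co-treated against doxorubicin hearts (0.0142). With the length trend removed 8 rose and 2 fell with doxorubicin. The glutathione peroxidases Gpx1 and Gpx3 rose by 1.34 ± 0.13 and 1.28 ± 0.21 on the log2 scale (SE) and the haem-degrading Hmox1 by 0.99 ± 0.21, while catalase, Cat, was at -0.58 ± 0.11. Ferritin heavy chain, Fth1, a member of the iron handling list, rose by 0.96 ± 0.13. In co-treated against doxorubicin hearts Gpx1 was at -1.22 ± 0.13, Hmox1 at -0.95 ± 0.21 and Cat at 0.73 ± 0.11. The list of 22 angiogenesis and growth factor genes was called in neither comparison (camera adjusted p = 0.462 and 0.0875). Of its members the angiogenic factor Vegfa was at -1.15 ± 0.14 with doxorubicin and 0.87 ± 0.14 in co-treated against doxorubicin hearts, and the growth factor Igf2 at 1.33 ± 0.13 and -0.93 ± 0.13.

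Of 6 sex-linked genes 0 rose and 3 fell with doxorubicin (0 and 3 adjusted over the list alone), at camera adjusted p = 0.0123 (adjusted p = 0.48 with an estimated correlation), or 0.053 without doxorubicin library 4, and in co-treated against doxorubicin hearts 2 rose and 0 fell (3 and 0 adjusted over the list alone), at 0.00851 (adjusted p = 0.48 with an estimated correlation). This list joins the X-linked Xist and Tsix with Y-linked genes. With doxorubicin 0 of 6 lay above control, and 6 of 6 lay above doxorubicin in co-treated hearts. A shift of all members in 1 direction is therefore not a measure of sex. With the length trend removed the median log2 fold change with doxorubicin went from -0.59 to -0.32. T and NK cell markers were called upward with doxorubicin at 0.045 (adjusted p = 0.72 with an estimated correlation), with 1 of 21 risen and 1 fallen (0 and 0 adjusted over the list alone), or 0.062, 0.2, 0.053 and 0.11 without control library 7, control library 8, doxorubicin library 2 and doxorubicin library 4, and 0.07 with the length trend removed. Of 8 epicardial markers 0 rose and 3 fell in co-treated against doxorubicin hearts (0 and 5 adjusted over the list alone), at 0.0494 (adjusted p = 0.48 with an estimated correlation), or 0.059, 0.055, 0.078, 0.15, 0.1 and 0.071 without doxorubicin libraries 2, 4 and 6 and co-treated libraries 2, 3 and 4. The keratin Krt8 had 0 counts in co-treated hearts, 1.77 CPM in doxorubicin hearts (edgeR adjusted p = 0.00525, at least 33.4-fold) and 4.18 CPM in control hearts (at least 79-fold), and it did not pass against control (0.0673).

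Genes past the test with opposite signs in doxorubicin against control and co-treated against doxorubicin hearts numbered 3077. The groups were separate hearts, so no gene was seen to change and then return. With the length trend removed 2282 genes were opposed, 74.2% of that number, and 1827 of them (59.4% of the 3077) were the same genes. With libraries thinned to the smallest total the number was 3085, or 100.3%, with 2963 the same genes, and with no library shared at least 89.7% of the called genes had opposite signs. These values argue against the length trend, depth and the shared libraries as the whole cause. They do not bear on other differences common to all 3 doxorubicin libraries, which cannot be told apart from the treatment. The real groups gave 5084, 4419 and 25 genes in the 3 comparisons, and of the 10 splits of each 6 libraries 1, the real one, gave as many, with 0, 1 and 0 genes as the highest other, but 10 splits are too few for a share under 0.05. The bacterium, by which the labels tell co-treated from doxorubicin hearts, stays open as an explanation and was not tested beyond the comparison itself. Other differences common to the 3 co-treated libraries cannot be told apart from the bacterium. Skeletal muscle fibre genes and the clock genes Dbp and Per3 were also higher than control in that group.

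The skeletal muscle fibre signal may come from skeletal muscle tissue in the co-treated samples. Of 12 fibre genes at up to 10 CPM in heart, 11 (91.7%) were higher in every co-treated library than in every other library, with a median SD of 0.23 (log2) among co-treated libraries, and the exception was Neb, at 2.92, 5.56 and 3.54 CPM in control, doxorubicin and co-treated hearts. This count repeats the rise that prompted the question, so it cannot tell such tissue from a change within heart muscle. Of the 14 list genes, heart expresses 2, Myl1 and Eno3, above 10 CPM, and 1, Eno3, is in another list. The most abundant were Myh4 at 80.5 and Atp2a1 at 52.9 CPM. The median log2 fold change against control was 4.48, and 4.44 with the length trend removed, which argues against that trend, while a change within heart muscle itself was not tested.

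Co-treated library 3 held 1610 CPM of Nppa and 14280 CPM of Myh7. On a scale from the control mean at 0 to the doxorubicin mean at 1, over genes called without it, this library lay at 0.3, against 0.17 and 0.19 for co-treated libraries 2 and 4 and 0.74 to 0.82 for doxorubicin libraries, which argues against a mislabelled doxorubicin heart. The highest of the atrial genes Myl7, Sln and Myl4 was at 1.03 CPM in it, which argues against atrial tissue as the source. A difference between animals stays open and may be the source, and was not tested.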
